A study of Homo sapiens with 44 samples.

How the data were processed

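The samples were 44 human small cell and neuroendocrine carcinomas of the bladder, kept as formalin-fixed, paraffin-embedded tissue. RNA was measured with Ion AmpliSeq transcriptome libraries per the labels' protocols, a method that counts 1 short amplicon per gene. The labels place the tumours in 3 batches, called A, B and C here, of 24, 6 and 14 tumours. No label assigns a tumour to a subtype and there are no normal tissue samples, so no groups of tumours were made.

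The deposited values are in log2 units, after normalization and batch adjustment by the authors, who left the method and order of the batch adjustment unstated. Raised back from the log scale and lowered by 1, the values of each tumour were whole multiples of a single step (100% of values, tolerance 0.1 of a step). The deposited log2 values therefore equal log2(x + 1), where x is an adjusted count divided by a size factor per tumour, and not raw reads. DESeq2 and the genome build hg19 are named, without a version or a role, per the submitters' processing notes; the aligner and the counting program are not given in the sources used here. The design made before the data were examined had allowed for a log2 scale, so its test was used as written. The table held 20802 genes for each tumour, and 20.1% of its values were exact zeros. XIST, TSIX and the Y-linked genes, 75 in all, were left out.

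Depth was taken from the adjusted counts, since raw totals were not used here. Totals ran from 2889183 to 15300709 with a median of 6150246, and 15434 to 18591 genes per tumour were above 0 (median 16494). The first count above 0 corresponds to a log2 value between 0.45 and 1.67 depending on the tumour, so differences among values below that are not resolved. The 10 highest genes took 5.34% to 21.4% of a tumour's total. Amplicon reads carry no molecular identifiers, so the p-values rest on the spread between tumours and not on counting error.

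Each gene was fitted against the level of a lineage factor, such as NEUROD1 or POU2F3, with batch as a covariate, in limma 3.58.1 under R 4.3.3 (lmFit, eBayes with a trend, 2-sided moderated test, Benjamini-Hochberg adjustment, threshold 0.05). Slopes are in log2 units per SD of the factor over the 44 tumours; the SDs were 3.80 for NEUROD1 and 4.14 for POU2F3. A gene was tested where at least 5 tumours reached a linear value of 10, which left 16960 genes. Differences between slopes were tested as contrasts in 1 model that holds the factors together. Some genes are not reported here, nor are the results that need them; they were kept in the joint models and in the adjustments for multiple tests, and left out of the counts of lists. Differences between batches were tested with limma's F test. Correlations between factors used values centred within batch, with 2-sided permutation tests of 100000 resamples, for which 1e-05 is the smallest p they can give, and exact enumeration for the 6 tumours of batch B. Principal components were taken from the 2000 most variable genes. Tables were handled with data.table (version 1.17.8), and figures drawn with matplotlib 3.10.9 and numpy 2.4.6 under Python 3.11.15.

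Before the data were examined, 25 gene lists were written, with 277 memberships, of which 258 could be tested. Those reported cover neuroendocrine genes, genes associated with NEUROD1 in small cell lung cancer, tuft cell, YAP1 pathway, luminal urothelial, basal and squamous, epithelial adhesion, mesenchymal transition, fibroblast, smooth muscle, endothelial, T and NK cell, B and plasma cell, myeloid, MHC class I and class II, interferon, immune checkpoint, proliferation, Notch, MYC family, drug target, prostate and immediate early genes. SSTR2 stands in 2 of them, the NEUROD1-associated genes and the drug targets. Lists with at least 5 tested members, 23 of them, were tested with camera (limma) at a preset correlation between genes of 0.01, adjusted over the 69 tests of lists and factors, and again with an estimated correlation. The other 2, the MYC family and the prostate list, were counted only. Also fixed before the data were examined were the tests, the filter and the other settings to be tried: no filter, a filter of 22 tumours (13261 genes), quantile normalization, robust eBayes, no batch covariate, batch A or C alone, leaving out the 2 tumours farthest from the factor's median, normal scores, the factors in 1 model, and leaving out each tumour in turn. Other pseudocounts, the number of genes detected as a covariate, voom weights, leaving out tumours 8, 9 and 16 together, fits of ATOH1 and YAP1, and the tests of patterns in the closing part, with bootstrap bounds for medians, were added after the data had been seen.

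The genes named for each factor follow a rule fixed before the data were examined. It takes the 10 rising and the 5 falling genes with the largest slopes among those past the test with the same sign in each batch fitted alone, up to 4 members of each list that passed, and fixed markers: NEUROD1, POU2F3, YAP1, ATOH1, CHGA, SYP, INSM1, NCAM1, DLL3, RB1 and REST. List members named beyond that rule are the ones past the test adjusted over the list alone, or examples with their values. A gene is said to rise or fall with a factor only where its slope passed the test.

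The slope test was tested on simulated data, with slopes added to 50 genes of each size over the spread of these tumours. For slopes of 0.5, 1, 1.5 and 2 it recovered 32%, 70%, 92% and 96% with NEUROD1 and 26%, 70%, 86% and 100% with POU2F3. The share of false calls was 4.61% and 6.62%. Tumours were shuffled within batch for each gene separately, which removes the relations between genes, so these shares hold for the simulated data only. The contrast of POU2F3 and NEUROD1 was not tested in this way. Slopes of 0.5 were thus mostly missed, and a gene outside the called ones is not shown to be unrelated to a factor.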

Results

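The data are transcriptome profiles of 44 bladder cancers of small cell or neuroendocrine type, in 3 batches of 24 (A), 6 (B) and 14 (C) tumours. Totals of adjusted counts per tumour ran from 2889183 to 15300709, with batch medians of 6439450, 8782695 and 5526828, and between 15434 and 18591 genes per tumour were above 0. The pairwise correlation of tumours over genes had a median of 0.775 (range 0.578 to 0.913). The study's title says that subtypes of this cancer are set by lineage transcription factors. The comparisons below therefore ask how the factors are distributed over the tumours, whether they exclude each other, and which genes go with the level of each. All samples are tumours, so every comparison is between tumours.

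NEUROD1, a basic helix-loop-helix factor that drives neuronal differentiation, and POU2F3, the master regulator of chemosensory tuft cells, each ranged from 0 in some tumours to log2 values above 10 in others. NEUROD1 had a median log2 value of 2.81 (up to 10.51) and reached a linear value of 10 in 20 of 44 tumours, and POU2F3 a median of 0.59 (up to 12.18), reaching 10 in 15. Both reached 10 in 4 tumours. YAP1, a coactivator of the Hippo pathway, reached 10 in 43 tumours, with a median of 7.54 (range 1.60 to 10.66). ATOH1, the factor of Merkel and hair cells, reached it in 12, with a median of 0.93 (up to 9.42). These counts describe the tumours and were not used as groups.

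Markers of neuroendocrine cells were present in most tumours. SYP, a synaptic vesicle protein, reached 10 in 44 tumours (median 8.60, range 3.62 to 10.20). INSM1, a zinc finger factor of neuroendocrine cells, reached it in 41 (median 10.82), the adhesion molecule NCAM1 in 43 (median 9.22), CHGA, the granule protein chromogranin A, in 37 (median 8.75, up to 15.28), and DLL3, an inhibitory Notch ligand and drug target, in 41 (median 7.60). RB1, the retinoblastoma tumour suppressor, had a median of 7.65 and REST, a repressor of neuronal genes, a median of 6.80. By batch, the NEUROD1 medians were 4.40, 3.48 and 0.82, and the POU2F3 medians 0, 4.41 and 1.28.

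**Figure D1:**
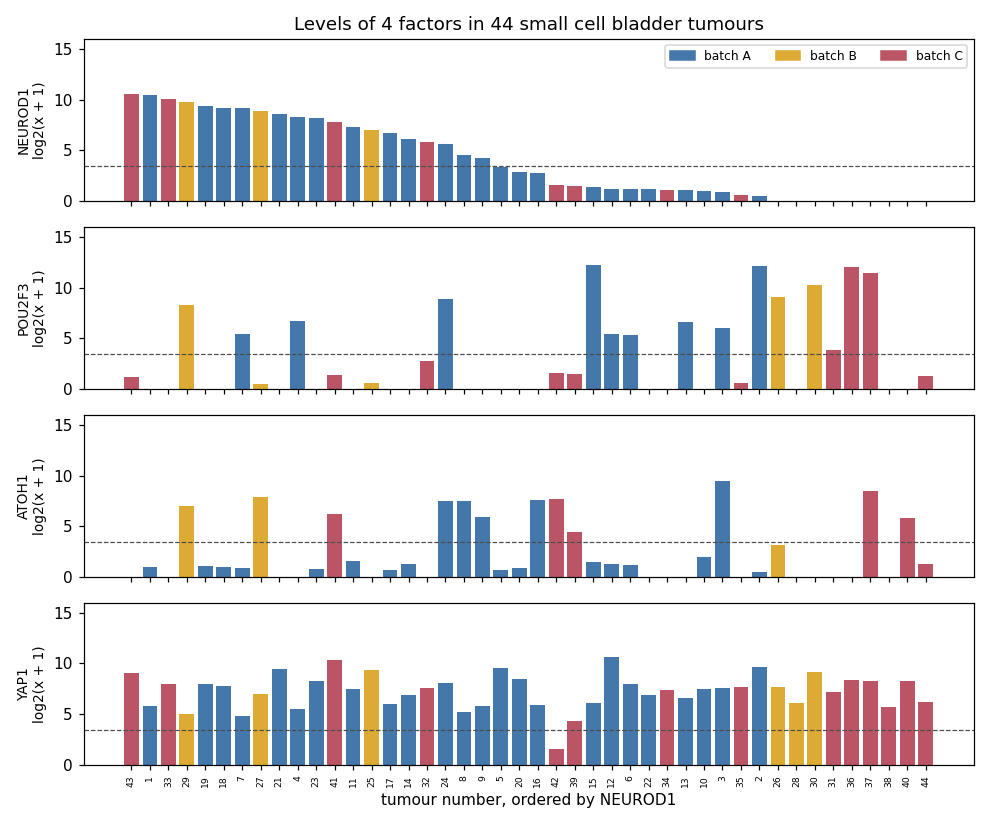
Levels of NEUROD1, POU2F3, ATOH1 and YAP1 in each of the 44 tumours, as deposited log2 values (vertical axes). Tumours are ordered by NEUROD1 and coloured by batch, and the dashed line marks a linear value of 10 (3.46). NEUROD1 reaches the line in 20 tumours, POU2F3 in 15, ATOH1 in 12 and YAP1 in 43.

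The next comparison asked whether the factors exclude each other. NEUROD1 and POU2F3 were not shown to do so. Their r was -0.340 (n = 44, permutation p = 0.0309, adjusted 0.103 over 10 pairs) and Spearman's rho -0.339 (permutation p = 0.0434, adjusted 0.191). Without the 2 tumours farthest from the NEUROD1 median r was -0.325, and rho in batches A, B and C was -0.387, -0.213 and -0.183. The 5 other pairs of NEUROD1, POU2F3, YAP1 and ATOH1 had adjusted p for rho between 0.264 and 0.811.

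ATOH1 levels were lower in tumours with larger adjusted count totals (n = 44, rho = -0.468, permutation p = 0.00251, adjusted 0.0251 over 10 relations; r = -0.321, adjusted 0.194; r without 2 tumours -0.425; rho by batch -0.594, 0.273 and -0.747). For POU2F3 and that total, rho was -0.396 (permutation p = 0.0110, adjusted 0.0552) and r was -0.217 (permutation p = 0.172, adjusted 0.514).

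The largest axis of variation between tumours had neuroendocrine genes at one end, and at the other tuft cell genes together with YAP1 pathway, MYC family and some of the immune lists. The first principal component held 9.86% of the variance of the 2000 most variable genes, with CEACAM5, the carcinoembryonic antigen, SEZ6L, DDC and CHGA at one end and RGS13, LRMP and POU2F3 at the other. Its rank correlation with the mean of the neuroendocrine list was 0.790 (n = 44, permutation p = 1e-05, the smallest the permutations can give, adjusted 2.1e-04 over all components, factors and lists; r = 0.831, adjusted 1.68e-04; r without 2 tumours 0.787; rho by batch 0.852, 0.829 and 0.741). With the tuft cell list rho was -0.507 (permutation p = 6.3e-04, adjusted 0.00378; r = -0.644, adjusted 1.68e-04; r without 2 tumours -0.579; rho by batch -0.356, -0.771 and -0.358). The YAP1 pathway list had a rho of -0.593 (permutation p = 3e-05, adjusted 4.2e-04; r = -0.536, adjusted 0.00231; r without 2 tumours -0.522; rho by batch -0.533, -0.371 and -0.859). The T and NK cell list had a rho of -0.510 (permutation p = 4.6e-04, adjusted 0.00297; r = -0.507, adjusted 0.00301; r without 2 tumours -0.445; rho by batch -0.421, -0.371 and -0.776), and the 3 MYC genes one of -0.534 (permutation p = 1.7e-04, adjusted 0.00143; r = -0.497, adjusted 0.00362; r without 2 tumours -0.551; rho by batch -0.562, -0.257 and -0.604). The MHC class I list had a rho of -0.418 (permutation p = 0.00508, adjusted 0.0203; r = -0.438, adjusted 0.0116; r without 2 tumours -0.393; rho by batch -0.390, -0.714 and -0.508). For the B and plasma cell list rho was -0.388 (permutation p = 0.00936, adjusted 0.0320; r = -0.457, adjusted 0.00943; r without 2 tumours -0.348; rho by batch -0.520, -0.429 and -0.424). For interferon response it was -0.369 (permutation p = 0.0148, adjusted 0.0463; r = -0.381, adjusted 0.0330; r without 2 tumours -0.313; rho by batch -0.270, -0.429 and -0.706), and for the epithelial list 0.389 (permutation p = 0.00951, adjusted 0.0320; r = 0.357, adjusted 0.0510; r without 2 tumours 0.376; rho by batch 0.257, 0.543 and 0.218). The third component, 6.80% of the variance, followed the NEUROD1-associated list (rho = -0.617, permutation p = 1e-05, adjusted 2.1e-04; r = -0.687, adjusted 1.68e-04; r without 2 tumours -0.668; rho by batch -0.631, -0.657 and -0.512). It followed the epithelial list with the opposite sign (rho = 0.534, permutation p = 2.9e-04, adjusted 0.00203; r = 0.454, adjusted 0.00943; r without 2 tumours 0.436; rho by batch 0.528, 0.714 and 0.450). The third component also went with the number of genes detected (rho = -0.391, permutation p = 0.00931, adjusted 0.0279; r = -0.381). Other immune lists did not pass on the first component. By permutation, myeloid genes had a rho of -0.219 (adjusted p = 0.2975), checkpoint genes -0.267 (adjusted p = 0.168) and MHC class II genes -0.198 (adjusted p = 0.3545). List members can be among the 2000 genes, so these relations describe the components and are not independent of them. Tumours 8, 9 and 16 stood apart from the rest along the second component, with a gap of 23.2% of its range, and no pooled relation is given for it.

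The NEUROD1 comparison asked which genes go with the level of this factor. Tumours with more NEUROD1 had more NEUROD4, a related neuronal differentiation factor (slope 2.64 ± 0.28, SE, log2 units per SD of NEUROD1, n = 44, adjusted p = 3.04e-08). They also had more PPP1R17, a phosphatase inhibitor of cerebellar neurons (2.63 ± 0.32, adjusted p = 9.30e-07). CHRNA1, the alpha subunit of the muscle acetylcholine receptor (2.14 ± 0.27, adjusted p = 2.47e-06), rose too, and so did ZEB1, a repressor of epithelial genes (0.78 ± 0.17, adjusted p = 0.0234). Examples of falling genes were TFF3, a secreted trefoil peptide (-1.67 ± 0.37, adjusted p = 0.0284), AP1M2, an adaptor subunit of epithelial sorting (-1.63, adjusted p = 0.0465), and CBLC, an epithelial ubiquitin ligase (-1.47, adjusted p = 0.0435).

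In all, 27 genes rose and 18 fell with NEUROD1 of 16960 tested, each with the same sign in the 3 batches fitted alone (812 and 706 at an unadjusted p under 0.05). The other rising genes of the naming rule were CERKL (2.24, adjusted p = 0.00114), the gene next to NEUROD1 in GRCh38.p14, FNDC5, the precursor of irisin (1.79), the cation channel gene TRPC5 (1.69), POPDC3 (1.67), a gene the file calls M1 (adjusted p = 0.0177), and MYOG, the muscle factor myogenin (1.49, adjusted p = 0.0452). The other falling ones were ARHGEF38 (-1.47) and CNKSR3 (-1.39, adjusted p = 0.00315). None of the fixed markers passed, with SYP at 0.20 (adjusted p = 0.927), CHGA 0.24 (0.967), INSM1 0.16 (0.979), NCAM1 -0.027 (0.997), DLL3 -0.20 (0.950), POU2F3 -1.43 (0.407), RB1 0.31 (0.845), REST 0.024 (0.997), ATOH1 -0.094 (0.988) and YAP1 0.0052 (0.998). Single tumours moved these counts: the rising count was 12 without tumour 43, 16 without 2, 17 without 27 and 43 without 33, and the falling count 1 without 43, 4 without 2, 7 without 18 or 22, 8 without 19, 9 without 1, 13, 15, 27 or 41, 10 without 4, 6, 7, 11, 20, 37 or 44, 11 without 5 or 17, 28 without 29 or 30, and 30 without 33. Tumour 43 also set the highest adjusted p of the genes that lost their call when a tumour was left out, MYOG (0.244, call lost in 22 of 44 cases), AP1M2 (0.147, 25 cases), CBLC (0.103, 16), ARHGEF38 (0.0967, 23) and TFF3 (0.0773, 7), and, lost in 1 case each, POPDC3 and M1 (0.113) and ZEB1 (0.0967).

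Epithelial genes moved down with NEUROD1 as a list. Of 9 epithelial adhesion and keratin genes 0 passed over all genes with limma (7 at an unadjusted p under 0.05), and 5 fell adjusted over the list alone: the splicing factor ESRP1 (-1.21), CLDN7 (-0.92), EPCAM (-0.55) and the keratins KRT8 and KRT18 (-0.65 each). The median slope was -0.65 (camera adjusted p = 7.55e-10, adjusted p = 0.0137 with an estimated correlation). The NEUROD1-associated genes of small cell lung cancer went up: 1 of 10 rose over all genes, NEUROD4, while 6 rose and 1 fell adjusted over the list alone, with a median slope of 1.01 (adjusted p = 1.53e-07, adjusted p = 0.00301 with an estimated correlation). NHLH2 stood at 1.34, the somatostatin receptor gene SSTR2 at 1.13, and LMO3, the one that fell, at -0.79. Of 7 mesenchymal transition genes 1 rose, ZEB1, and 2 rose adjusted over the list alone, ZEB1 and ZEB2 (0.85), with a median slope of 0.33 (adjusted p = 0.0126, adjusted p = 0.291 with an estimated correlation).

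With NEUROD1, 4 more lists passed the preset test with 0 members past limma's test over all genes; at an unadjusted p under 0.05 there were 5 tuft cell, 1 luminal, 2 MHC class II and 2 immediate early genes. Tuft cell genes had a median slope of -0.45 (1 of 19 fell adjusted over the list alone, adjusted p = 3.18e-05, and adjusted p = 0.432 with an estimated correlation). Luminal urothelial genes stood at -0.30 (1 of 15 fell adjusted over the list alone, ELF3 at -1.10, adjusted p = 0.0144, and adjusted p = 0.611 with an estimated correlation). MHC class II genes stood at -0.38, each of the 9 below 0, among them CD74 at -0.48 (0 adjusted over the list alone, adjusted p = 0.00211, and adjusted p = 0.560 with an estimated correlation). Immediate early genes stood at 0.40, with FOS at 0.57 and each of the 7 above 0 (0 adjusted over the list alone, adjusted p = 0.0101, and adjusted p = 0.432 with an estimated correlation). Of the 7 lists past the preset test 2 held with an estimated correlation, the epithelial and the NEUROD1-associated one, and levels reassigned at random gave as many lists. The rest did not pass (adjusted p between 0.0548 and 0.950). Neuroendocrine genes had a median of -0.093, a mean of 0.026 and a test pointing down, YAP1 pathway 0.20, basal -0.12 and proliferation 0.068. Stromal lists had medians of -0.0090 for fibroblast, 0.029 for smooth muscle and -0.057 for endothelial genes. T and NK cell genes stood at -0.18, B and plasma cell genes at -0.11 and myeloid genes at -0.15, each with an upper bootstrap bound below 0. That bound resamples the genes of a list and not the tumours, so it does not show a fall with NEUROD1. With camera the adjusted p of these lists was 0.405, 0.413 and 0.109. MHC class I genes stood at -0.11, interferon at -0.23 (1 fell adjusted over the list alone), checkpoint at -0.0080 and Notch at -0.13. Drug targets had a median of -0.18 (1 rose adjusted over the list alone, SSTR2), the 3 MYC genes 0.62 (1 rose adjusted over the list alone, MYCL1 at 0.97), and the 3 prostate genes -0.44.

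The POU2F3 comparison asked which genes go with the tuft cell factor. Tumours with more POU2F3 had more of the genes that mark tuft cells. C11orf53, now named POU2AF2, a coactivator of POU2F3, rose by 2.62 ± 0.30 per SD (n = 44, adjusted p = 1.51e-07), the kinase gene BMX by 2.24 ± 0.32 (adjusted p = 1.95e-05), and TRPM5, the taste channel, by 1.82. RGS13, a regulator of G protein signalling, had the largest slope (3.15 ± 0.52, adjusted p = 2.69e-04). Among the falling genes were several of neurons and neuroendocrine cells: the potassium channel gene KCNH7 (-2.45 ± 0.32, adjusted p = 4.54e-06) and the granule protein genes CHGA (-1.85 ± 0.48, adjusted p = 0.0432) and CHGB (-1.62, adjusted p = 0.0123).

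In all, 113 genes rose and 61 fell with POU2F3, 111 and 59 with the same sign in each batch (856 and 1061 at an unadjusted p under 0.05). The other rising genes of the naming rule were the homeobox gene HMX3 (2.37, adjusted p = 0.00252), FAM150A, a ligand of the ALK receptor (2.23), LRMP (2.13), PLA2G4A, the phospholipase that releases arachidonic acid (2.11), the collagen gene COL2A1 (2.09, adjusted p = 0.00603), SH2D6 (2.05) and the ETS factor SPIB (2.03). The other falling ones were the neurexin relative CNTNAP2 (-1.99, adjusted p = 0.0312) and the zinc finger gene ZIC2 (-1.99, adjusted p = 0.0181). Among the fixed markers CHGA alone passed; INSM1 had a slope of -1.44 (adjusted p = 0.175), NEUROD1 -1.27 (0.316), NCAM1 -0.83 (0.256), DLL3 -0.56 (0.574), SYP -0.50 (0.441), REST 0.66 (0.117), YAP1 0.21 (0.858), ATOH1 0.28 (0.896) and RB1 -0.16 (0.899). Leaving out 1 tumour lowered the rising count to 50 (tumour 2), 70 (37) or 72 (15) and the falling count to 28 (tumour 2), 30 (37), 37 (28) or 39 (15). It ended the call of CHGA in 19 of 44 cases (highest adjusted p = 0.143, without tumour 37), CNTNAP2 in 7 (0.0842, 37), ELAVL4 in 6 (0.138, 15), CHGB in 3 (0.0821, 2), SYT1 in 2 (0.0976, 2) and ZIC2 in 1 (0.0552, 2). Without tumours 8, 9 and 16 together CHGA (adjusted p = 0.0641) and ELAVL4 (0.0573) were no longer called.

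Of 19 tuft cell genes 14 rose and 0 fell with POU2F3 over all genes, and 15 rose and 1 fell adjusted over the list alone, the latter DCLK1 (-0.65). The median slope was 1.32 (camera adjusted p = 1.47e-33, adjusted p = 1.44e-05 with an estimated correlation). Besides those above they include CHAT, which makes acetylcholine (1.76), GFI1B (1.66), SOX9 (1.54), the prostaglandin enzyme PTGS1 (1.41) and the interleukin receptor IL17RB (1.20). Of 22 neuroendocrine genes 4 fell, CHGA, CHGB, the neuronal RNA-binding ELAVL4 (-1.48, adjusted p = 0.0374) and SYT1, a calcium sensor of vesicle release (-1.30, adjusted p = 0.0125). Adjusted over the list alone 11 of the 22 fell, with a median slope of -0.78 (adjusted p = 9.50e-09, and adjusted p = 0.168 with an estimated correlation). None of 10 MHC class I genes passed over all genes with limma (3 at an unadjusted p under 0.05), 2 rose adjusted over the list alone, the immunoproteasome gene PSMB9 (0.99) and the peptide transporter TAP1 (0.81), and the median was 0.39 (adjusted p = 4.08e-04, and adjusted p = 0.432 with an estimated correlation). Of these 3 lists the tuft cell list alone held with an estimated correlation, and levels reassigned at random gave as many lists.

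The other lists did not pass with POU2F3 (adjusted p between 0.109 and 0.902). Median slopes were -0.34 for NEUROD1-associated genes, 0.12 for the YAP1 pathway, 0.29 for luminal urothelial, 0.16 for basal, 0.20 for epithelial adhesion and -0.23 for mesenchymal transition genes. Stromal lists stood at 0.0062 for smooth muscle and -0.18 for endothelial genes, and fibroblast genes had a median of -0.017 with a test pointing up. T and NK cell genes stood at 0.23, B and plasma cell genes at 0.12, myeloid genes at 0.018, MHC class II at 0.23, interferon response at 0.020 and checkpoint genes at 0.10. Proliferation genes stood at -0.096, immediate early genes at -0.13 and Notch genes at 0.024, where NOTCH1 and REST rose adjusted over the list alone. Drug targets had a median of 0.076, a mean of -0.14 and a test pointing up, the 3 MYC genes a median of 0.26 and a mean of -0.0014, and the 3 prostate genes a median of 0.62, with ACPP and TMPRSS2, an androgen-regulated protease, rising adjusted over the list alone.

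**Figure D2:**
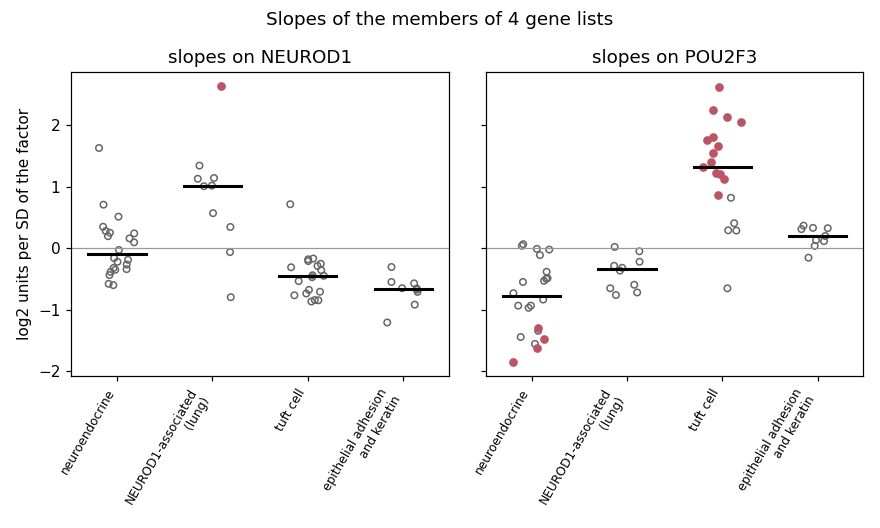
Slopes of list members on NEUROD1 and POU2F3 (vertical axes, log2 units per SD of the factor) for 4 of the fixed lists. Each point is 1 gene, filled where it passed the test over all genes, and the bar marks the list's median. Tuft cell genes stand at a median of 1.32 on POU2F3, and epithelial genes at -0.65 on NEUROD1.

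The last comparison of factors asked which genes differ in slope between POU2F3 and NEUROD1, in a model that holds the factors together. The examples are genes named for the single factors. Slopes on POU2F3 were higher for C11orf53, the coactivator gene of tuft cells (2.25, adjusted p = 3.77e-04), and for the epithelial CBLC (adjusted p = 0.00386). They were lower for NEUROD4 (-2.43, adjusted p = 5.39e-05), CHRNA1 (-2.24, adjusted p = 1.15e-04) and ZEB1 (-0.88, adjusted p = 0.0137).

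In all, 145 genes differed between POU2F3 and NEUROD1, 95 with the higher slope on POU2F3 and 50 on NEUROD1. Of the 27 genes rising with NEUROD1, 19 had a different slope on POU2F3, and of the 113 rising with POU2F3, 48 had a different slope on NEUROD1. The rest of the called genes are not shown to belong to 1 factor. Leaving out 1 tumour lowered the count to 28 (tumour 2), 57 (15), 63 (43), 85 (37) or 90 (13).

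A last comparison asked what difference between the batches was left after the authors' adjustment. CHST13, a chondroitin sulfotransferase gene, was higher in batch A (mean log2 3.52) than in B (0) and C (0.19), with an adjusted p of 1.68e-08 by limma's F test. It was the single gene of 16960 past the test, and 2 passed without tumour 26. At an unadjusted p under 0.05 there were 62 genes, fewer than the 848 that chance gives in values without any batch adjustment. The slopes above are fitted with batch in the model.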

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

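The tests of this part were chosen after the slopes within each batch had been seen. The slopes of the fixed markers were compared between batch A (24 tumours) and batch C (14 tumours) with an interaction term in limma, adjusted over 33 slopes.

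On NEUROD1, the slope of SYP, the synaptic vesicle marker, was 0.85 in batch A and -0.87 in batch C, a difference of -1.71 (adjusted p = 0.0431). On POU2F3, CHGA had slopes of -0.57 and -3.45, a difference of -2.89 (adjusted p = 0.0495).

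Over all 16960 genes, 0 and 1 differed between these batches in their slopes on NEUROD1 and POU2F3 (limma), with 823 and 1386 at an unadjusted p under 0.05 against 848 by chance. CHGA is therefore called as falling with POU2F3 over all tumours on slopes of unequal size. The pooled slope of SYP on NEUROD1 joins slopes of opposite sign. No explanation of these differences was tested.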

How the results depend on the processing

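The alternatives with other pseudocounts, the number of genes detected as a covariate, voom weights, leaving out tumours 8, 9 and 16 together, and leaving out tumours in the batch test were chosen after seeing the data; the others were planned. Under quantile normalization (9 counts and correlations, 51 slopes of named genes), robust eBayes (8 and 51) and no batch covariate (7 and 51), each kept its direction, its side of the threshold and, for counts, a size within 1.5 times. Fewer of the 51 slopes did so in other settings: 25 in batch A alone and 21 in batch C alone. Without the 2 tumours farthest from the factor's median 28 did so, with normal scores 40, with the factors in 1 model 30, and with voom weights 38. Most of the remaining slopes were weaker. No result reversed in any alternative run, and the genes called as rising or falling with NEUROD1 or POU2F3 kept the sign of their slope in every alternative that fitted them, apart from leaving out single tumours, where signs were not counted.

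Where counts moved further, the values were as follows; the cause was not tested, except that fewer genes are tested with a stricter filter and fewer tumours enter within a batch. Without a filter 9 genes fell with NEUROD1. With a filter of 22 tumours 7 rose and 8 fell with NEUROD1, 57 rose with POU2F3, 87 differed between POU2F3 and NEUROD1, and 0 between batches (limma, 2 at an unadjusted p under 0.05). In batch A alone 53 rose with NEUROD1, 3 rose and 2 fell with POU2F3, and 87 differed in slope. In batch C alone 0 rose and 0 fell with NEUROD1 (limma, 446 and 313 at an unadjusted p under 0.05), 9 rose and 6 fell with POU2F3, and 1 differed in slope, with 4 lists for NEUROD1 and 6 for POU2F3. Without the 2 tumours farthest from the factor's median 11 rose and 1 fell with NEUROD1, 18 rose and 12 fell with POU2F3, and 4 differed in slope. With normal scores the counts were 15 and 8 for NEUROD1, and 63 and 24 for POU2F3. With the factors in 1 model they were 7 and 1 for NEUROD1, and 41 and 9 for POU2F3. With an estimated correlation, camera called 2 lists for NEUROD1 and 1 for POU2F3.

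Of the added alternatives, a pseudocount of 0.5 gave 11 genes falling with NEUROD1. A pseudocount of 10 gave 53 rising with NEUROD1, 205 rising with POU2F3, and 232 differing between POU2F3 and NEUROD1. With the number of genes detected as a covariate 29 fell with NEUROD1, and 5 lists moved with POU2F3. With voom weights 42 rose and 11 fell with NEUROD1, and 254 rose and 29 fell with POU2F3. Without tumours 8, 9 and 16, which stand apart on the second component, 34 fell with NEUROD1 and 91 differed between POU2F3 and NEUROD1. The correlation of NEUROD1 and POU2F3 did not pass the threshold in any alternative.

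Leaving out each tumour in turn gave ranges of 12 (without tumour 43) to 43 (33) genes rising and 1 (43) to 30 (33) falling with NEUROD1, and 50 (2) to 134 rising and 28 (2) to 80 falling with POU2F3. For slope differences the range was 28 (2) to 171. For differences between batches it was 1 to 2 (26). No paired analysis was made because the labels used here give no pairing of samples. Depth limits the genes near 0: the first count lies between 0.45 and 1.67 log2 units, and 20.1% of values are zeros.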

Other observations

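The fits of ATOH1, YAP1 and the HOX clusters, leaving out tumours 8, 9 and 16, and the counts of reassigned levels for the genes rising and falling with each factor and for batches were chosen after results had been seen, as were the 2 patterns below and the list of 5 epithelial genes; the tests of the patterns were written before their results.

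In the preset test YAP1, the coactivator of the Hippo pathway, went with fibroblast, smooth muscle and immune lists and against neuroendocrine genes. No list held with an estimated correlation. The endothelial list did not pass the preset test, and its difference from the other lists was not tested. With YAP1, 418 genes rose and 80 fell (2012 and 894 at an unadjusted p under 0.05), among them LUM, a proteoglycan of fibroblasts (1.53), DES, the muscle filament desmin (1.56), CXCL13, a B cell chemokine (1.63), CD8A of T cells (1.42) and IGLL5 of plasma cells (1.92). INSM1 fell (-1.76), and so did ELAVL4 (-1.57), SEZ6, a drug target (-1.42), and CHGB (-1.34). Of 12 fibroblast genes 7 rose and 10 rose adjusted over the list alone, with a median slope of 0.73 (camera adjusted p = 2.91e-11, and adjusted p = 0.0714 with an estimated correlation). Of 10 smooth muscle genes 5 rose, 7 adjusted over the list alone, with a median of 0.89 (adjusted p = 1.16e-07, and adjusted p = 0.101 with an estimated correlation). Of 22 neuroendocrine genes 7 fell, 11 adjusted over the list alone, with a median of -0.75 (adjusted p = 3.29e-09, and adjusted p = 0.121 with an estimated correlation). Of 8 YAP1 pathway genes 2 rose, 5 adjusted over the list alone, with a median of 0.53 (adjusted p = 8.56e-04, and adjusted p = 0.0997 with an estimated correlation). None of 8 endothelial genes passed over all genes with limma (3 at an unadjusted p under 0.05) or over the list alone, with a median of 0.29 (adjusted p = 0.118).

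Of the immune lists with YAP1, 1 of 11 T and NK cell genes rose, 4 adjusted over the list alone, with a median of 0.76 (adjusted p = 4.95e-05, and adjusted p = 0.315 with an estimated correlation). None of 9 B and plasma cell genes passed over all genes with limma (5 at an unadjusted p under 0.05), 5 rose adjusted over the list alone, and the median was 0.73 (adjusted p = 0.00521, and adjusted p = 0.315 with an estimated correlation). Of 13 myeloid genes 3 rose, 6 adjusted over the list alone, with a median of 0.53 (adjusted p = 1.29e-04, and adjusted p = 0.320 with an estimated correlation). Of 10 interferon genes 4 rose, 9 adjusted over the list alone, with a median of 0.84 (adjusted p = 3.06e-07, and adjusted p = 0.121 with an estimated correlation). Of 10 MHC class I genes 2 rose and of 9 class II genes 2, 5 of each adjusted over the list alone, with medians of 0.59 and 0.55 (adjusted p = 0.00112 and 4.15e-04, and 0.320 and 0.315 with an estimated correlation). None of 7 checkpoint genes passed over all genes with limma (3 at an unadjusted p under 0.05), 3 rose adjusted over the list alone, and the median was 0.56 (adjusted p = 0.00521, and adjusted p = 0.315 with an estimated correlation).

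Of the other lists with YAP1, 2 of 7 Notch genes rose, 4 adjusted over the list alone, with a median of 0.46 (adjusted p = 0.00475, and adjusted p = 0.175 with an estimated correlation). Of 7 mesenchymal transition genes 1 rose, also adjusted over the list alone, with a median of 0.49 (adjusted p = 0.0171, and adjusted p = 0.255 with an estimated correlation). Of 10 NEUROD1-associated genes 0 passed over all genes with limma (2 at an unadjusted p under 0.05), 1 fell adjusted over the list alone, and the median was -0.50 (adjusted p = 0.00195, and adjusted p = 0.130 with an estimated correlation). Of 15 proliferation genes 0 passed over all genes with limma (2 above 0 and 4 below at an unadjusted p under 0.05) or over the list alone, and the median was -0.13 (adjusted p = 0.0178, and adjusted p = 0.538 with an estimated correlation). The other lists with YAP1 did not pass (adjusted p between 0.0734 and 0.834), and 0 lists held with an estimated correlation. Leaving out tumour 42 lowered the rising count to 203, and tumour 25 raised the falling count to 152, while tumour 5 lowered it to 50. Without tumours 8, 9 and 16 the counts were 341 and 56, and DES and CHGB were no longer called.

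With ATOH1, 51 genes rose and 81 fell (1006 and 1526 at an unadjusted p under 0.05). POU4F3, the hair cell factor, rose most (2.16, adjusted p = 3.00e-04), and GFI1, a zinc finger factor of the same cells (1.23), LHX3 (1.33), DRGX (1.39) and POU3F4 (1.29) are examples of the others, as are the metallothionein genes MT1G (1.15) and MT1A (0.79). IRX3 (-1.38) and IRX5 (-1.17), homeobox genes of the Iroquois family, fell. Tumours 8, 9 and 16, which stand apart on the second component, are among the 12 that reach 10 for ATOH1, at 7.46, 5.90 and 7.57. Without these 3 the counts were 30 and 38, and of the transcription factor genes GFI1, POU3F4 and IRX3 were no longer called. Leaving out 1 tumour moved the rising count to 18 (tumour 8), 29 (16), 33 (42) or 103 (40) and the falling count to 24 (tumour 8), 43 (16), 51 (37), 126 (3) or 149 (40). ATOH1 also went with the adjusted count total, as given with the factor correlations.

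With ATOH1, 3 lists passed the preset test, each with 0 members past limma's test over all genes. Proliferation genes had a median slope of -0.20 (4 of 15 at an unadjusted p under 0.05, 0 adjusted over the list alone, adjusted p = 0.00195, and adjusted p = 0.320 with an estimated correlation). NEUROD1-associated genes stood at 0.32 (1 of 10 at an unadjusted p under 0.05, 1 rose adjusted over the list alone, adjusted p = 0.0403, and adjusted p = 0.320 with an estimated correlation). Basal and squamous genes stood at 0.22 (4 of 14 at an unadjusted p under 0.05, 1 rose adjusted over the list alone, adjusted p = 0.0403, and adjusted p = 0.495 with an estimated correlation).

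Of the HOX genes, which set position along the body axis, 5 of 7 in the HOXC cluster rose with POU2F3, from HOXC5 (0.98) to HOXC10 (1.98). Of the other clusters, 2 of 11 HOXA genes rose, HOXA2 (1.04) and HOXA3 (0.85), 0 of 8 HOXB genes passed (limma, 0 at an unadjusted p under 0.05), and 1 of 8 HOXD genes fell, HOXD10 (-1.21). No difference between clusters was tested. With NEUROD1 0 of 34 passed (limma, 2 at an unadjusted p under 0.05). Under quantile normalization 0 members of the HOXC cluster on POU2F3 changed sign.

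CHRNA1, MYOG, TNNC1 (1.12) and MYBPHL (1.21), genes of muscle but not all of skeletal muscle alone, rose with NEUROD1, with a median slope of 1.35. CHRNA1 kept its call without each tumour in turn (limma, highest adjusted p = 4.901e-05, without tumour 43). For CHRNA1 the tables argue against a single tumour as the source. Without tumour 43 MYOG (adjusted p = 0.244), MYBPHL (0.152) and TNNC1 (0.113) were no longer called. Their slopes stayed above 0, at 1.095, 1.005 and 1.024. They reach 10 in 7, 8 and 7 tumours, and MYOG lost its call in 22 of 44 cases. The highest unadjusted p of the 4 genes without any 1 tumour was 0.0016 (MYOG, without tumour 43). The genes were chosen for small p in these same tumours, so that p does not settle how far their rise rests on tumour 43. Skeletal muscle tissue in the samples may contribute and stays open: the 14 tested contractile genes of a list written before the test had a median slope of 0.61 with an upper bound of 0.955, and the 0.68 that such tissue would need lies inside their bounds. Of them 0 passed (limma, 6 at an unadjusted p under 0.05), with TNNC2 at 1.39, ACTA1, the actin of muscle fibres, at 0.84 and MB, myoglobin, at -0.35. The bladder wall holds smooth muscle, whose list had a median of 0.029, and TPM2 of the contractile list is made there too; no biological explanation was tested.

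Epithelial genes, 5 of 9 adjusted over the list alone, fell with NEUROD1, with a median slope of -0.65, and 0 of the 5 changed sign under quantile normalization. A lower share of tumour cells would raise the markers of the other cell types alike. Such a rise was not seen: the 6 lists ran from -0.18 to 0.029, and the lowest upper bound was -0.0648, for myeloid genes. These bounds resample genes and not tumours, and with camera none of the 6 lists passed (adjusted p between 0.109 and 0.950). A lower share of tumour cells is therefore not excluded. A lower share of urothelial cells beside the tumour cells is a candidate explanation that stays open, since the 29 luminal and basal genes had a median of -0.25 with a lower bound of -0.476, and the -0.33 it would need lies inside the bounds. A state of the tumour cells themselves was not tested.

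Levels of each factor were reassigned to tumours within batches, and batch labels over all tumours, in 99 random ways beside the real one. For the number of genes called with each factor, 1 of 100 assignments, the real one, gave as many. This concerns the counts over all 44 tumours and not any single gene. Without tumour 43 the falling count of NEUROD1 was 1, and levels were not reassigned without that tumour. The real counts and the highest of the others were 27 and 1 (rising) and 18 and 1 (falling) for NEUROD1, 113 and 1 and 61 and 1 for POU2F3, 51 and 15 and 81 and 6 for ATOH1, and 418 and 44 and 80 and 1 for YAP1. For slope differences they were 145 and 0. Chance cannot be excluded for the number of lists past the preset test: 15 and 71 of 100 assignments gave as many as the 7 and 3 lists of NEUROD1 and POU2F3, with highest others of 13 and 12. Nor can it be for the number of genes between batches, 1, which 10 of 100 assignments reached (highest other 23). That compares numbers of genes and leaves aside the strength of CHST13, with its adjusted p of 1.68e-08.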
